A study of Mus musculus with 15 samples.

How the data were processed

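Submandibular glands of 15 mice were profiled by RNA sequencing, with 5 libraries from untreated ICR mice (control), 5 from untreated NOD/LTJ mice (model) and 5 from NOD/LTJ mice given SJQYD. Per the labels, RNA was extracted with Trizol, selected with oligo-dT beads, made into strand-specific libraries with molecular identifiers in the adapters, and sequenced as paired reads of 150 bases. The submitters' notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, without the order or role of each. They name the mouse build mm9, but the coordinates in the FPKM table equal those of GRCm38 for 29470 of 32385 genes found in the reference annotation (91.0%), so coordinates are given in GRCm38.

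The authors deposited a matrix of whole-number gene counts for 55401 genes, of which 22922 have no count in any library. A second table by the authors gives FPKM values, scaled to gene length and library size, for the other 32479 genes, together with the same counts. Small counts pile up at 4, which occurs 14040 times against 8483 for 3 and 4460 for 5, so that totals are not read as numbers of molecules. The total count per library ran from 39510018 to 68694263, and 3 counts, taken as the floor below which a gene could not be seen, correspond to 0.0290 to 0.0840 CPM on the TMM-adjusted scale. Such floors cover counting error only. They may be too low, as the pile-up at 4 leaves open that a read pair adds several counts. The notes name UMI-tools without saying whether duplicate reads were removed with it. The least different pair of libraries in the same group had a chi-square of 79.3 per gene, so no library was a copy of another.

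Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by the default filter on expression by group, which left 18136. Libraries were scaled by TMM factors, and a quasi-likelihood model with robust estimation and one mean per group was fitted to all 15 libraries, so that the 3 groups shared the estimate of the spread. The F test was applied to model against control, SJQYD against model and SJQYD against control, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p values for genes are from this edgeR test. Normalised read counts (CPM) are scaled to the TMM-adjusted library size. A fold change is given on the log2 scale with its standard error, and means with their SD over 5 libraries.

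Gene lists for immune cells and responses, gland functions, adjoining tissues and cell processes, 38 in all, were written before the data were examined, as were the tests, the comparisons and the rule for naming genes. For 37 lists at least 5 genes were tested. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. A list member was also adjusted over its list alone. For each library the mean log2 CPM of the members, minus the control mean, gave a list score, and scores were compared by a two-sided exact permutation test over the 252 arrangements of 5 against 5 libraries, adjusted over lists within a comparison.

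The rule for naming genes took, for each comparison, up to 10 genes with the largest rise and 10 with the largest fall among called genes with at least 5 CPM in the higher group, at least a 2-fold change and no overlap between the groups. Unnamed genes, predicted genes, pseudogenes marked as such and segments of antigen receptor genes were not named but stayed in the counts. Up to 4 members with the smallest p were named for each list described, and Aqp5, Chrm3, Egf, Cxcl13, Cd3e and Ighm were always given, with 2 further genes of this rule not reported here. Xist and Y-linked genes served as a check of sex.

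Genes called in both of the first 2 comparisons were set beside n1 × n2/N, beside 20 simulations with unchanged groups, and beside 20 divisions of the model libraries between the comparisons. On simulated data with 200 changed genes, the edgeR test recovered 49% of 2-fold and 93% of 4-fold changes for model against control, with 8 false calls among 150, and 62% and 90% for SJQYD against model, with 3 false calls among 155. Alternatives tried were other normalizations, other filters on low counts, DESeq2 1.42.0, voom with quality weights, a fit of only the 2 groups compared, limma on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, a replicate block and leaving out each library. The FPKM fits kept 12436 genes with at least 0.5 FPKM in 5 libraries, or all 32479. The scores of 3 adjoining tissues as covariates, and a fit without 3 libraries, were added after the data were seen. KEGG sets of 15 to 300 genes, 290 in all, were also tested after the data were seen.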

Results

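RNA of the submandibular gland, a salivary gland, was sequenced in 15 mouse samples, 5 in each of 3 groups. The control group held untreated ICR mice, an outbred stock, and the model group held untreated NOD/LTJ mice, a strain that develops autoimmune inflammation of the salivary glands. The third group held NOD/LTJ mice given SJQYD, a treatment that the labels name only by these letters. The series title places the work in Sjögren's syndrome, a disease in which immune cells enter the salivary glands. Each sample is a separate library, and the labels do not say more about how the mice relate to each other. Total counts per library ran from 54836440 to 63101584 in the control group, from 52746925 to 68694263 in the model group and from 39510018 to 62335235 in the SJQYD group. After filtering, 18136 genes were tested.

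A single secretory transcript took much of each library. Mucl2, a mucin-like product of the gland, held 48.4% ± 5.07 (SD, n = 5) of all counts in the control group, 37.3% ± 7.74 (SD, n = 5) in the model group and 36.8% ± 12.3 (SD, n = 5) in the SJQYD group. The share ranged over single libraries from 15.5% in SJQYD 1 to 53.8% in control 3. Amy1, Bpifa2, Smr3a and Chia1, which are abundant in the adjoining parotid gland, were chosen after their values were seen. Together they held 16.0% of the counts in model 3, 6.50% in SJQYD 1 and 4.17% in control 2, against 2.11% in model 1 and at most 0.623% in every other library. Spearman correlations between libraries ran from 0.922 to 0.969 over the tested genes. Xist, the RNA of the inactive X chromosome, stood at 1.01 CPM, a normalised read count, in SJQYD 3 and between 162 and 270.2 CPM in the other 14 libraries.

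**Figure D1:**
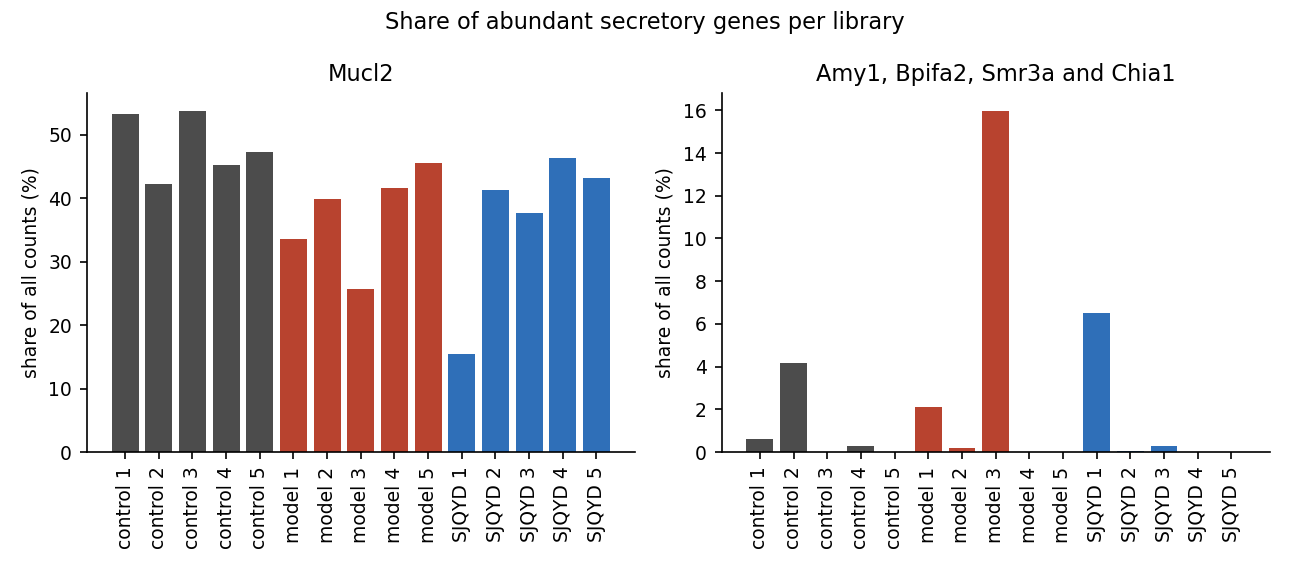
Share of all counts (%, vertical axes) held by Mucl2 (left) and by Amy1, Bpifa2, Smr3a and Chia1 together (right) in each of the 15 libraries, one bar per library and one colour per group. Mucl2 was lowest in SJQYD 1 at 15.5%, and the 4 genes on the right were highest in model 3 at 16.0%.

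The comparison of model with control asks how the glands of untreated NOD/LTJ mice differ from those of ICR mice, and strain and disease cannot be told apart in it. Some genes of the interferon response, antigen presentation and cytotoxic lymphocytes rose in the model glands and some genes of protein folding in the endoplasmic reticulum fell. Camera calls for these lists were lost with an estimated correlation (adjusted p = 0.253 for each). Mx1 (ENSMUSG00000000386), an antiviral protein induced by type I interferon, rose from 1.77 ± 0.553 to 5.90 ± 2.87 normalised CPM (SD, n = 5 per group), a log2 fold change of 1.74 ± 0.33 (SE). B2m (ENSMUSG00000060802), the light chain of MHC class I, rose from 122 ± 49.5 to 344 ± 98.0 CPM (SD, n = 5 per group). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 238 ± 48.3 to 130 ± 31.1 CPM (SD, n = 5 per group). In all, edgeR called 920 genes, 466 higher and 454 lower, of which 253 and 110 differed at least 2-fold. Over all tested genes 1046 (5.77%) had no overlap between the groups, where chance gives 0.794%.

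Of 22 tested genes induced by interferon gamma, 10 rose and 0 fell, and 20 rose when adjusted over the list alone (camera adjusted p = 1.64e-12, adjusted p = 0.253 with an estimated correlation). They included Iigp1, a GTPase that attacks parasite vacuoles (log2 fold change 1.92 ± 0.29 SE, edgeR adjusted p = 0.00221), Psmb8, a subunit of the immunoproteasome (1.68 ± 0.30, adjusted p = 0.0064), and Cd274, which encodes PD-L1 (1.54 ± 0.31, adjusted p = 0.0114). Among 32 genes induced by type I interferon, 7 rose and 24 rose adjusted over the list alone, with Ifit1 at 1.95 ± 0.32 (adjusted p = 0.003), Zbp1 at 1.99 ± 0.44 and Irf7 at 1.19 ± 0.28 (camera adjusted p = 1.17e-10, adjusted p = 0.253 with an estimated correlation). Among 24 genes of antigen presentation, 8 rose, and adjusted over the list alone 15 rose and 1 fell (camera adjusted p = 1.17e-10, adjusted p = 0.253 with an estimated correlation). Tap1, a peptide transporter, rose by 1.35 ± 0.28, H2-Q4 by 1.43 ± 0.27 and Cd86, a costimulatory ligand of T cells, by 1.22 ± 0.21. MHC haplotypes differ between strains, which bears on H2 genes.

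Of 26 genes of NF-kB signalling and cytokines, 7 rose and 13 rose adjusted over the list alone, with Nfkb2 at 0.82 ± 0.14 and the adhesion molecules Icam1 at 1.09 ± 0.22 and Vcam1 at 1.15 ± 0.27 (camera adjusted p = 2.47e-07, adjusted p = 0.253 with an estimated correlation). Of 15 genes of cytotoxic T and natural killer cells, 4 rose and 6 rose adjusted over the list alone (camera adjusted p = 4.41e-06, adjusted p = 0.253 with an estimated correlation). Ctsw rose by 2.07 ± 0.34, the chemokine Ccl5 by 2.09 ± 0.48 and Nkg7, a protein of cytotoxic granules, by 1.36 ± 0.37. Among 22 plasma cell genes 3 rose and 8 rose adjusted over the list alone, with the transcription factor Irf4 at 1.80 ± 0.43 and Tnfrsf13b, a receptor for B cell survival factors, at 1.58 ± 0.41 (camera adjusted p = 2.44e-05, adjusted p = 0.253 with an estimated correlation). Among 24 myeloid genes 3 rose and 9 rose adjusted over the list alone, including Fcgr1 at 1.01 ± 0.22 and Batf3 at 1.95 ± 0.37 (camera adjusted p = 9.48e-05, adjusted p = 0.262 with an estimated correlation). Of 21 genes of Toll-like receptors and the inflammasome, 3 rose, with Casp1 at 1.24 ± 0.25 and Tlr7 at 1.60 ± 0.34, and 6 rose adjusted over the list alone (camera adjusted p = 0.0365, adjusted p = 0.253 with an estimated correlation). This call was lost without control 2, control 5 or model 1 (adjusted p = 0.0555, 0.0624 and 0.0901).

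Lymphocyte markers varied widely between libraries. Control 2 stood at 3.08 for the B cell score and 2.60 for the T cell score. The other controls ran from -2.51 to 0.53 and from -1.44 to 0.001, and the model libraries from 2.20 to 3.36 and from 0.99 to 3.73. Control 2 thus lay within the range of the model libraries in both scores. None of 20 B cell genes and none of 24 T cell genes passed the test singly, over all genes or adjusted over the list alone (0 and 0 genes), although camera placed both lists higher (adjusted p = 1.46e-08 and 1.58e-07, adjusted p = 0.279 and 0.425 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, stood at 4.68 ± 4.36 CPM in the model group and 1.03 ± 1.58 CPM in the control group (SD, n = 5 per group, edgeR adjusted p = 0.214). Ighm, the heavy chain of IgM, had a log2 fold change of 2.08 ± 0.60 (adjusted p = 0.0648) and Cxcl13, a chemokine that draws B cells, 2.34 ± 0.74 (adjusted p = 0.0869). Of 18 genes of lymphoid organisation none passed over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.000584, adjusted p = 0.383 with an estimated correlation).

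Of 24 genes of endoplasmic reticulum stress and protein folding 8 fell and 0 rose, and adjusted over the list alone 16 fell and 2 rose (camera adjusted p = 2.39e-07, adjusted p = 0.253 with an estimated correlation). Hspa5 fell by 0.87 ± 0.18 on the log2 scale (SE), Manf, a secreted survival factor, by 0.63 ± 0.14 and the disulfide isomerase Pdia3 by 0.53 ± 0.13. Syvn1, a ubiquitin ligase of the endoplasmic reticulum, fell by 0.45 ± 0.11, though its direction turned with FPKM values (0.03). Of 18 acinar genes 2 fell, over all genes and adjusted over the list alone: Bhlha15, a transcription factor of secretory cells, by 0.57 ± 0.15, and Prlr, the prolactin receptor, by 0.76 ± 0.18, without a camera call for the list (adjusted p = 0.198), whose median was -0.09 and mean 0.03. Hspa5, Manf, Pdia3, Syvn1, Bhlha15 and Prlr were not called with FPKM values, which follow the total count. Among 30 nuclear genes of the respiratory chain 1 fell, Atp5g1, by 1.16 ± 0.18, and 1 fell adjusted over the list alone (camera adjusted p = 0.00301, adjusted p = 0.512 with an estimated correlation, and 0.0856 without control 5). Of 10 skeletal muscle genes 3 rose, over all genes and adjusted over the list alone, among them Ryr1, a calcium release channel, at 2.74 ± 0.73 and Eno3 at 0.88 ± 0.24 (camera adjusted p = 0.017, adjusted p = 0.253 with an estimated correlation). The score of this list passed the exact permutation test (adjusted p = 0.0367). All model libraries, at 0.63 to 1.40, lay above all control libraries, at -0.41 to 0.34. Muscle lies next to the gland, and whether it was carried over was not tested. Lists of blood, fat and nerve were placed higher by camera as well. Of 5 erythrocyte genes 1 rose and 2 rose adjusted over the list alone (camera adjusted p = 0.00522, adjusted p = 0.278 with an estimated correlation), and the score of the list passed the exact permutation test (adjusted p = 0.0489). Of 16 adipocyte genes 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.639 with an estimated correlation, and 0.0677 and 0.318 without control 2 and model 2). Of 14 nerve and Schwann cell genes 1 rose and 4 rose adjusted over the list alone (camera adjusted p = 0.0454, adjusted p = 0.383 with an estimated correlation, and 0.0524 to 0.103 without control 1, 2 or 5, model 1 or 2 or SJQYD 2).

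Of 23 products of the granular duct 0 were called, also adjusted over the list alone, although camera placed the list lower (adjusted p = 0.00522, adjusted p = 0.508 with an estimated correlation). The list's score rested on model 4, at -2.13 against -0.31 to 0.39 in the other model libraries. Without model 4 the model mean moved from -0.51 to -0.11 and the camera call was lost (adjusted p = 0.0968), as it was without control 5 (adjusted p = 0.0513). Egf, a growth factor of these ducts, stood at 114 ± 44.7 CPM in the model group and 252 ± 197 CPM in the control group (SD, n = 5 per group, edgeR adjusted p = 0.255). Aqp5, the water channel of acinar cells, stood at 342 ± 63.8 and 400 ± 59.1 CPM (adjusted p = 0.444), and Chrm3, the receptor that drives fluid secretion, at 6.37 ± 1.66 and 7.40 ± 3.76 CPM (adjusted p = 0.868). The direction of Aqp5 and Chrm3 turned with FPKM values.

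Some of the largest folds lay in genes that have near-identical copies in the genome, for which reads can be assigned to another copy. Rpl26 (ENSMUSG00000060938, GRCm38 chromosome 11, 68901583 to 68906989), a ribosomal protein gene, stood at 376 ± 29.5 CPM in the model group and 11.3 ± 2.80 CPM in the control group (SD, n = 5 per group), a log2 fold change of 5.06 ± 0.18 (SE, adjusted p = 1.28e-11). The natural killer cell receptor genes Klra1 and Klra7 rose by 5.02 ± 0.69 and 4.87 ± 0.55, Mup5, a major urinary protein gene, by 5.80 ± 1.13, the light chain gene Iglc1 by 4.06 ± 0.91 and Slpi, a protease inhibitor, by 3.46 ± 0.81. Mup5 stood at 1008 CPM in model 4 and between 45.9 and 127 CPM in the other model libraries. Its log2 fold change was 4.12 without model 4. Without control 4 those of Klra1, Iglc1 and Slpi were 5.91, 5.395 and 4.66. Zgrf1, Psmc3ip, Tpm3-rs7 and Sphk1 rose by 2.59 to 3.28, with Tpm3-rs7 at 3.37 without control 1. Agr2 (ENSMUSG00000020581, GRCm38 chromosome 12, 35992907 to 36004087), a disulfide isomerase of mucus-secreting cells, fell by 4.79 ± 0.33 (adjusted p = 1.88e-07) and Uox, urate oxidase, by 5.62 ± 1.07 (7.01 without model 1). Rpl30 fell by 2.38 ± 0.22 and Ndufs5 by 1.83 ± 0.14. Cry1, a repressor of the clock, fell by 1.03 ± 0.26, and Trim12c, Sdr39u1, Gucy2c, Tspan8, Ly6e and Rmnd1 had log2 fold changes from -2.37 to -1.66, with Tspan8 at -1.22 without control 5.

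For this comparison camera called 21 of 37 lists, 16 higher and 5 lower, and 0 with an estimated correlation, where fry called 17. The scores of 12 lists, averaged over list members in each library, differed past the exact permutation test after adjustment, 11 higher and 1 lower, and the smallest p this test can give is 0.00794. The lower one was autophagy (adjusted p = 0.0489), of which 0 of 20 genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.00501, adjusted p = 0.253 with an estimated correlation). The score of endoplasmic reticulum genes did not pass (adjusted p = 0.126). The number of list scores was 0 without any one of model 1, 2, 3, 4 and 5 and 0 with medians over members. Tests without a library had fewer arrangements, although 16 list scores passed without control 2. Whether the fewer arrangements or the model libraries lowered the number was not tested. Single libraries moved the number of genes from 354 without model 2 to 1799 without control 2, and it was 220 with parotid, sublingual and fat scores as covariates. With DESeq2 it was 1779, and with limma on log2(FPKM + 1) it was 1447, of which 97.2% were higher, against 50.7%. FPKM values follow the total count, of which Mucl2 held 48.4% in the control and 37.3% in the model group. They leave out the TMM factors, which ran from 0.594 to 1.01 in control and from 0.945 to 1.32 in model libraries. The median log2 fold change of all genes moved with them from 0.03 to 0.28. The share of 97.2% is therefore not read as a rise of most genes.

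**Figure D2:**
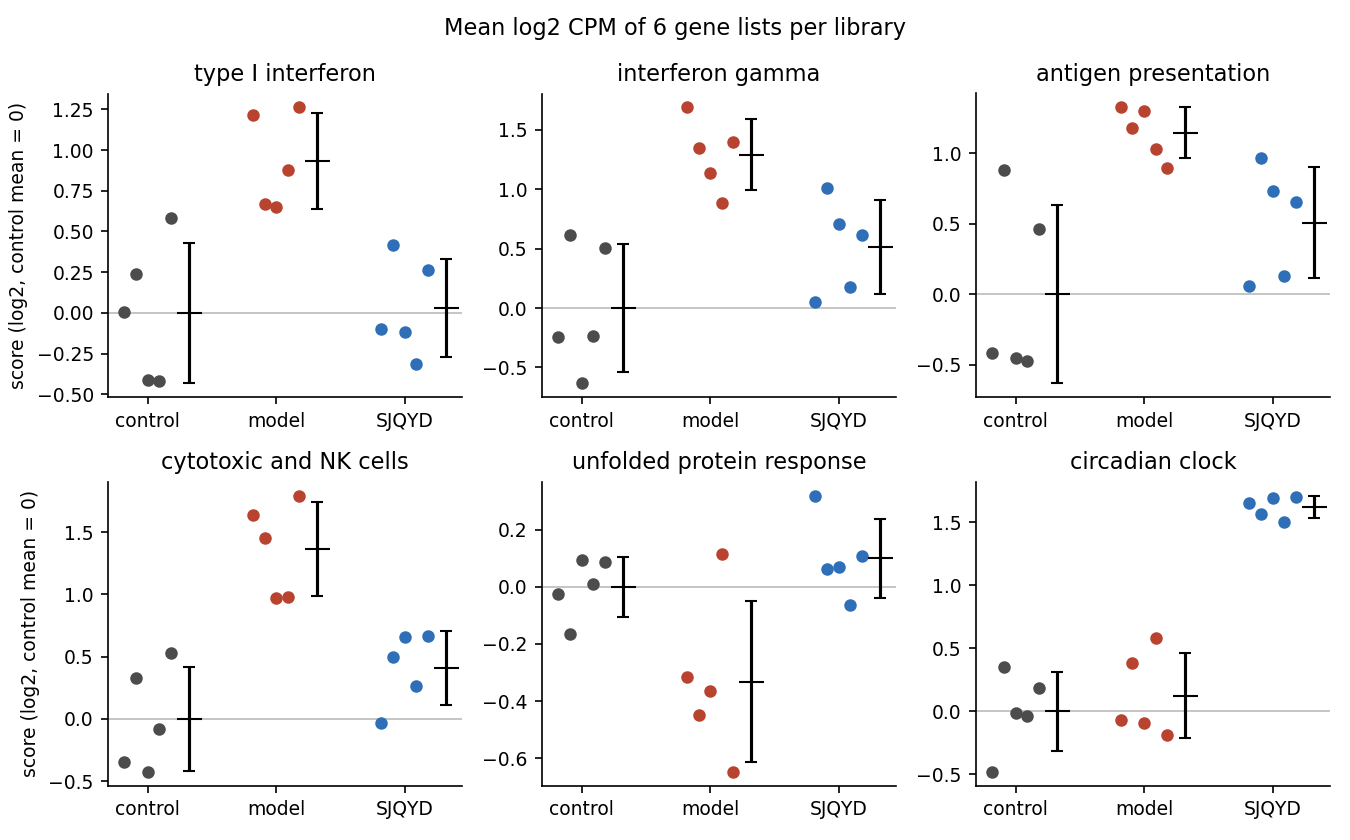
Scores of 6 gene lists per library (mean over list members of log2 CPM minus the control mean, vertical axes) by group, one point per library, with a horizontal line for the group mean and bars for the SD. The type I interferon score had a mean of 0.93 in the model group and 0.03 in the SJQYD group.

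The comparison of SJQYD with model asks what the treatment changed within NOD/LTJ mice. Genes of the circadian clock differed: Dbp, Per2, Per3 and Ciart, which the clock drives, were higher in the SJQYD glands, and Arntl and Npas2, which drive the clock, were lower. Dbp (ENSMUSG00000059824, GRCm38 chromosome 7, 45705088 to 45710203) rose from 7.57 ± 7.13 to 194 ± 42.0 CPM (SD, n = 5 per group), and Per2 (ENSMUSG00000055866) rose 16.4-fold, from 2.64 ± 1.16 to 43.3 ± 11.0 CPM (SD, n = 5 per group). Arntl (ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126) fell from 11.9 ± 5.78 to 0.915 ± 0.268 CPM (SD, n = 5 per group). Some genes induced by interferon fell and some genes of protein folding rose. Camera calls for the type I interferon, interferon gamma and folding lists were lost with an estimated correlation (adjusted p = 0.203, 0.264 and 0.193). In all, edgeR called 498 genes, 346 higher and 152 lower, of which 74 and 53 differed at least 2-fold. Over all tested genes 998 (5.50%) had no overlap between the groups, where chance gives 0.794%.

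Of 15 clock genes 10 rose and 3 fell, and adjusted over the list alone 12 rose and 3 fell. The list was called by camera (adjusted p = 9.40e-10) and stayed called with an estimated correlation (adjusted p = 0.0151). Per2 had a log2 fold change of 4.04 ± 0.35 (SE, edgeR adjusted p = 3.40e-05), Dbp 4.68 ± 0.87 (adjusted p = 0.0131, and 5.29 without model 4), Per3 3.36 ± 0.41 (adjusted p = 0.000598), Cry2 1.58 ± 0.17 (adjusted p = 0.000111) and Tef 2.85 ± 0.61 (adjusted p = 0.0256). Ciart, Per1 and Bhlhe41, which repress the clock, rose by 2.98 ± 0.41, 2.13 ± 0.34 and 2.05 ± 0.30. Arntl fell by 3.71 ± 0.44 (adjusted p = 0.000548) and Npas2 by 3.01 ± 0.35 (adjusted p = 0.000253). The score of the list averaged 1.63 ± 0.09 in the SJQYD group and 0.12 ± 0.34 in the model group (SD, n = 5 per group, exact permutation test, adjusted p = 0.042). The labels give no hour of collection for any group.

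**Figure D3:**
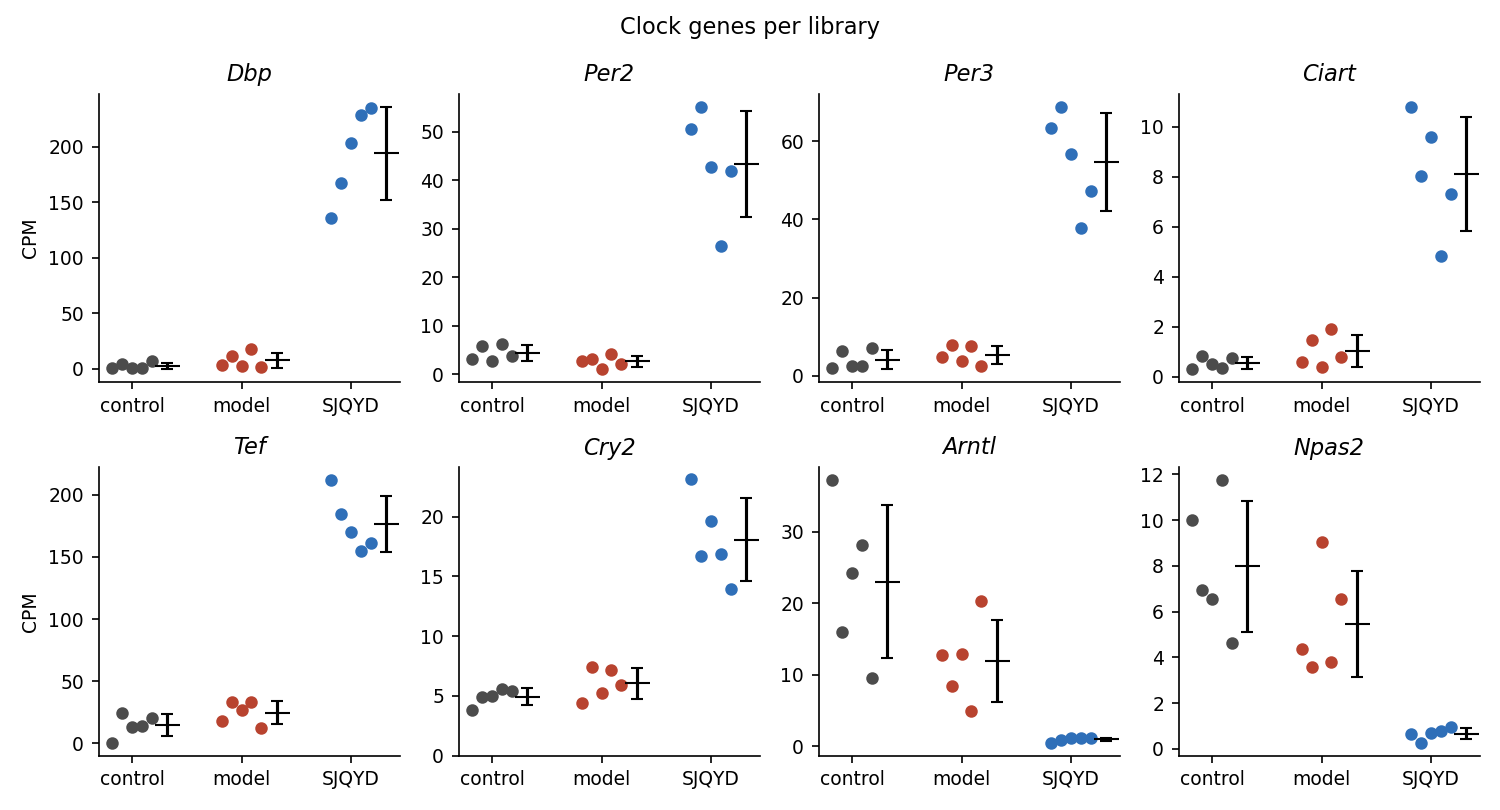
Normalised CPM (vertical axes) of clock genes in each library by group, one point per library, with a horizontal line for the group mean and bars for the SD. Dbp and Per2 stood at means of 194 and 43.3 CPM in the SJQYD group against 7.57 and 2.64 in the model group, and Arntl at 0.915 against 11.9.

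Of 32 genes induced by type I interferon 5 fell and 0 rose, and 27 fell adjusted over the list alone (camera adjusted p = 5.10e-13, adjusted p = 0.203 with an estimated correlation). Mx1 fell by 1.62 ± 0.32 on the log2 scale (SE, edgeR adjusted p = 0.0112), Oasl2, an antiviral protein, by 1.14 ± 0.24, Cmpk2 by 1.43 ± 0.32 and Ifit2 by 1.34 ± 0.33. Of 22 genes induced by interferon gamma 1 fell, the transcription factor Irf1, by 0.67 ± 0.13, and 11 fell adjusted over the list alone (camera adjusted p = 1.12e-08, adjusted p = 0.264 with an estimated correlation). Of 24 genes of antigen presentation 3 fell, B2m by 1.25 ± 0.24, the protease Ctss by 1.09 ± 0.25 and Cd86 by 0.83 ± 0.21, and 6 fell adjusted over the list alone (camera adjusted p = 1.23e-06, adjusted p = 0.371 with an estimated correlation). Of 26 NF-kB and cytokine genes 3 fell, Nfkb2 by 0.61 ± 0.14, Relb by 0.86 ± 0.22 and Birc3, an inhibitor of cell death, by 0.71 ± 0.18, and 5 fell adjusted over the list alone (camera adjusted p = 2.11e-05, adjusted p = 0.231 with an estimated correlation). The type I interferon score averaged 0.03 ± 0.30 in the SJQYD group and 0.93 ± 0.29 in the model group (SD, n = 5 per group), a difference with an exact permutation p of 0.00794 (adjusted p = 0.042). The scores of the interferon gamma and antigen presentation lists did not pass this test (adjusted p = 0.0587 for each). Mx1 and B2m were not called with FPKM values, whereas Dbp, Per2, Arntl and Npas2 were called on log2(FPKM + 1).

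Of 24 myeloid genes 2 fell, Itgam, an integrin of myeloid cells, by 1.41 ± 0.29 and C1qa, a complement subunit, by 0.61 ± 0.16, and 11 fell adjusted over the list alone (camera adjusted p = 6.04e-08, adjusted p = 0.159 with an estimated correlation). Of 15 cytotoxic genes 0 passed over all genes and 4 fell adjusted over the list alone (camera adjusted p = 2.11e-05, adjusted p = 0.159 with an estimated correlation). Among 25 apoptosis genes 1 fell, Bbc3, which promotes cell death, by 0.97 ± 0.24, and 3 fell adjusted over the list alone (camera adjusted p = 0.000369, adjusted p = 0.153 with an estimated correlation). None of 20 B cell, 24 T cell and 24 extracellular matrix genes passed, over all genes or adjusted over the list alone (0 in each list). Camera placed these 3 lists lower, with adjusted p = 0.00675, 0.00223 and 3.89e-05, and adjusted p = 0.687, 0.687 and 0.264 with an estimated correlation. The B cell call was lost without SJQYD 4 (adjusted p = 0.0552) and the T cell call without model 1, model 5 or SJQYD 4 (adjusted p = 0.0502, 0.0647 and 0.0534). Of 13 genes of the mitochondrial genome 0 passed, over all genes or adjusted over the list alone, and camera placed them lower (adjusted p = 0.0454, adjusted p = 0.687 with an estimated correlation). This call was lost without any one of 8 libraries (adjusted p from 0.0515 to 0.218), among them each of SJQYD 1, 2, 3 and 4. Cd3e stood at 1.57 ± 1.37 CPM in the SJQYD group and 4.68 ± 4.36 CPM in the model group (SD, n = 5 per group, edgeR adjusted p = 0.46), Ighm at 50.9 ± 25.9 and 96.9 ± 41.8 CPM (adjusted p = 0.481) and Cxcl13 at 3.07 ± 2.09 and 8.68 ± 2.74 CPM (adjusted p = 0.324).

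Of 24 genes of endoplasmic reticulum stress and folding 6 rose and 0 fell, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 7.87e-09, adjusted p = 0.193 with an estimated correlation). The score of this list did not pass the exact permutation test (adjusted p = 0.122). Dnajb9, a chaperone partner, rose by 1.35 ± 0.19 (edgeR adjusted p = 0.00082), Syvn1 by 0.87 ± 0.11 (adjusted p = 0.000547), Herpud1 by 1.03 ± 0.24 and Atf4, a transcription factor of the stress response, by 0.78 ± 0.14. Txndc5, a disulfide isomerase on the plasma cell list, rose by 0.63 ± 0.13. Of 23 antioxidant genes 2 rose, over all genes and adjusted over the list alone, Prdx6 by 0.74 ± 0.14 and Gsta3 by 1.54 ± 0.37, without a camera call for the list (adjusted p = 0.442), whose median was -0.03 and mean 0.01.

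Outside these lists, Usp2, a deubiquitinase, rose by 2.91 ± 0.22 (edgeR adjusted p = 4.85e-06), Coq10b by 1.95 ± 0.16 (adjusted p = 5.83e-06) and Mir22hg by 1.74 ± 0.22. Slc25a34, Tmem82, Tjp3 and Col5a3 had log2 fold changes from -1.93 to -1.53. Cx3cr1, the fractalkine receptor of myeloid cells, fell by 1.51 ± 0.22, Ly6a by 1.41 ± 0.32, Leo1 by 1.32 ± 0.15 and Bmf, which promotes cell death, by 1.32 ± 0.17. Aqp5 stood at 465 ± 79.9 CPM in the SJQYD group (SD, n = 5, adjusted p = 0.164 against the model group), Chrm3 at 4.75 ± 2.63 CPM (adjusted p = 0.787) and Egf at 102 ± 76.0 CPM (adjusted p = 0.928). The direction of Egf turned in some settings.

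For this comparison camera called 18 of 37 lists, 2 higher and 16 lower, where fry called 10 and 1 stayed with an estimated correlation. The scores of 7 lists passed the exact permutation test after adjustment, 1 higher and 6 lower. This number was 0 without model 1, model 5 or SJQYD 1, and 0 with medians over members or FPKM values. Tests without a library again had fewer arrangements. The number of genes was 1072 with DESeq2, 68 with limma on log2(FPKM + 1) and 186 without control 2, model 3 and SJQYD 1, the libraries highest in parotid genes, when Dbp and B2m were not called. The largest number without a single library was 527 and the smallest 333, without model 2.

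Genes called both in model against control and in SJQYD against model numbered 87, of which 77 moved in opposite directions. This number ran from 23 without model 2 to 128 without model 4. It was 30, 45 and 41 without control 1, 3 and 4, 32, 35 and 40 without model 1, 3 and 5, and 51, 46 and 42 without SJQYD 1, 3 and 4. With DESeq2 it was 206, and with FPKM values between 7 and 10. Of these, 22 were higher in the model glands and lower after SJQYD, among them Mx1, B2m, Cd86 and Nfkb2, and 55 were lower in the model glands and higher after SJQYD, among them Syvn1 and Pdia3. Products of the numbers called (n1 × n2/N) give 3.91 and 8.66 genes for these directions. Moving in the same direction were 10 genes, against 8.89 higher in both and 3.81 lower in both. Both comparisons use the same model libraries, which alone favours opposite signs. Over 20 simulations with unchanged groups, which kept these shared libraries, the covariance of the fold changes was -0.119 on average (-0.139 to -0.109), against -0.170 in the data. The simulations drew each gene on its own and so left out correlation between genes, which can make their ranges too narrow. Other measures, the correlation and the share of opposite signs, lay nearer to no relation in the data than in these simulations. The correlation was -0.357 against -0.497 (-0.535 to -0.462). In the data 60.1% of all tested genes had opposite signs against 66.6% (65.7 to 67.4%). With the model libraries split between the comparisons, 20 divisions gave 5.45 genes in opposite and 1.95 in the same direction on average. Their mean covariance was -0.0558. Of the opposite ones, 0.8 were higher and then lower and 4.65 lower and then higher, where n1 × n2/N gives 0.487 and 0.683. For the same direction it gives 0.826 higher in both and 0.419 lower in both.

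**Figure D4:**
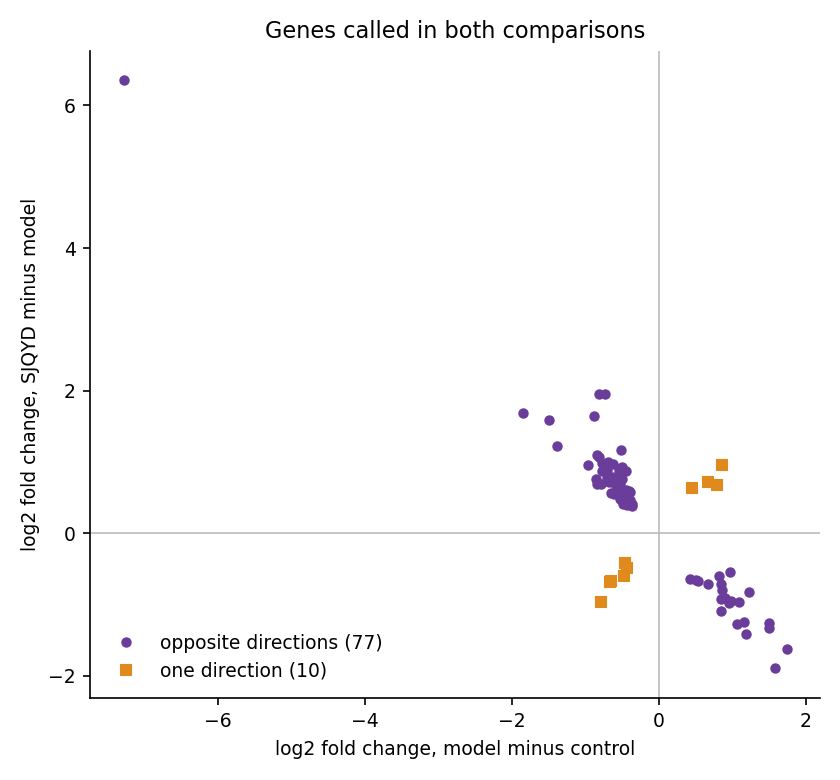
Log2 fold change of SJQYD against model (vertical axis) plotted on that of model against control (horizontal axis) for the 87 genes called in both comparisons, one point per gene. Of these, 77 lie in the quadrants of opposite sign and 10 in those of equal sign.

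The comparison of SJQYD with control asks how far treated NOD/LTJ glands differ from ICR glands. Clock genes differed here too: Dbp rose by 6.20 ± 0.95 on the log2 scale (SE, edgeR adjusted p = 0.00183) and Arntl fell by 4.66 ± 0.46 (adjusted p = 4.22e-05). Without control 5 the log2 fold change of Dbp was 6.94. Of 30 respiratory chain genes 10 fell and 15 fell adjusted over the list alone (camera adjusted p = 1.01e-05, adjusted p = 0.818 with an estimated correlation), among them Atp5g1, which fell from 73.2 ± 11.3 to 31.7 ± 4.51 CPM (SD, n = 5 per group). In all, edgeR called 2017 genes, 947 higher and 1070 lower, of which 331 and 260 differed at least 2-fold. Over all tested genes 1827 (10.1%) had no overlap between the groups, where chance gives 0.794%.

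Of 15 clock genes 11 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 3.22e-05, adjusted p = 0.175 with an estimated correlation). Per2 rose by 3.31 ± 0.34, Per3 by 3.72 ± 0.42, Ciart by 3.88 ± 0.43, Tef by 3.59 ± 0.63 and Cry2 by 1.87 ± 0.17, and Npas2 fell by 3.55 ± 0.36. Of the respiratory chain, Atp5g1, a subunit of ATP synthase, fell by 1.20 ± 0.18, and Uqcrfs1 and Uqcrc2, of complex III, fell by 0.68 ± 0.13 and 0.59 ± 0.13. The score of the respiratory chain list did not pass the exact permutation test (adjusted p = 0.176). Of 13 genes of the mitochondrial genome 0 passed, over all genes or adjusted over the list alone, and camera placed them lower (adjusted p = 0.028, adjusted p = 0.818 with an estimated correlation, median -0.42). This call was lost without control 1, 3 or 4 or SJQYD 1, 2 or 3 (adjusted p from 0.0549 to 0.112). Ndufb3, of complex I, fell by 0.52 ± 0.12, though its direction turned with FPKM values (0.02), with which Atp5g1, Uqcrfs1 and Uqcrc2 were not called. Of 22 plasma cell genes 3 rose, with Irf4 at 1.55 ± 0.43 and Iglc1 at 4.09 ± 0.91 (5.43 without control 4), and 4 rose adjusted over the list alone (camera adjusted p = 1.44e-05, adjusted p = 0.553 with an estimated correlation). Of 10 skeletal muscle genes 3 rose, over all genes and adjusted over the list alone, with Ryr1 at 2.67 ± 0.73 and Eno3 at 0.87 ± 0.24 (camera adjusted p = 0.0263, adjusted p = 0.31 with an estimated correlation).

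Of 22 genes induced by interferon gamma 3 rose, over all genes and adjusted over the list alone, among them Psmb8 at 1.04 ± 0.29 (camera adjusted p = 0.0247, adjusted p = 0.818 with an estimated correlation). The call was lost without control 1, 3 or 4 or SJQYD 2 or 3 (adjusted p from 0.0538 to 0.151). Of 24 genes of antigen presentation 3 rose, among them H2-Q4 at 1.02 ± 0.27 and Nlrc5, which switches on MHC class I genes, at 2.17 ± 0.44, and 1 fell, Ctss, by 1.01 ± 0.25, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.028, adjusted p = 0.818 with an estimated correlation). The call was lost without control 1, 3 or 4 or SJQYD 2, 3 or 5 (adjusted p from 0.0614 to 0.135). None of 20 B cell, 24 T cell and 23 granular duct genes passed, over all genes or adjusted over the list alone (0 in each list). Camera placed the first 2 lists higher and the duct list lower (adjusted p = 0.00401, 0.0263 and 0.013, and adjusted p = 0.818 for each with an estimated correlation). The T cell call was lost without control 3 or 4 or SJQYD 2 or 3 (adjusted p from 0.0622 to 0.335). Of 24 extracellular matrix genes 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.818 with an estimated correlation). Of 24 genes of endoplasmic reticulum stress and folding 5 rose and 1 fell, and adjusted over the list alone 5 rose and 3 fell, without a camera call (adjusted p = 0.958) and with a median of -0.07 and a mean of 0.10. Ddit3, which promotes cell death under stress, rose by 1.29 ± 0.24, Atf4 by 0.57 ± 0.14 and Syvn1 by 0.42 ± 0.11.

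Several genes with large folds in model against control had large folds here as well. Rpl26 rose by 4.94 ± 0.18 (SE), Mup5 by 4.55 ± 1.07 and Slpi by 3.67 ± 0.81 (4.87 without control 4). Agr2 fell by 4.70 ± 0.32 (edgeR adjusted p = 2.40e-07), Uox by 3.21 ± 0.94 (3.87 without SJQYD 2) and Rpl30 by 2.58 ± 0.22. Trim12c, Sdr39u1, Tspan8 and Ceacam10 had log2 fold changes from -3.15 to -2.37, with Tspan8 at -1.80 without control 5. Vil1 (ENSMUSG00000026175), an actin-binding protein of epithelial cells, fell by 6.51 ± 1.17 (adjusted p = 0.00436, and 7.34 without SJQYD 4). BC018473 rose by 6.67 ± 1.88 (adjusted p = 0.04), with control 3 far above the other 4 control libraries and a log2 fold change of 9.93 without it. Model against control and SJQYD against control shared 533 called genes, of which 526 moved the same way, 248 higher and 278 lower, where n1 × n2/N gives 24.3 and 26.8, and 7 moved in opposite ways. These comparisons share the control libraries. Simulations with unchanged groups, again with each gene drawn on its own, gave a covariance of the fold changes of 0.123, against 0.464 in the data. With the control libraries split, 108 genes moved the same way on average, with a mean covariance of 0.371.

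For this comparison camera called 13 of 37 lists, 7 higher and 6 lower, with 0 called with an estimated correlation and 3 by fry. The scores of 0 lists passed the exact permutation test after adjustment. The clock, plasma cell and skeletal muscle scores had the smallest p this test can give, 0.00794, which became 0.0979 after adjustment. So the test could not call these scores, although none of them overlapped between the groups. The number of genes ran from 1240 without control 5 to 2626 without control 2, and was 609 with the adjoining tissue scores as covariates. With limma on log2(FPKM + 1) it was 3626, of which 97.6% were higher, against 47.0%. Here too FPKM values leave out the TMM factors, which ran from 0.910 to 1.85 in SJQYD libraries.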

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

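The tests for time of day, for the shared model libraries and for Ndufs5, Rpl30 and Rpl26 were chosen after the result was seen. So were those for other splits of the libraries and for a swap of 2 libraries. The predictions for adjoining tissue, lymphocytes and pseudogenes were written before the results of their own tests were seen. The parotid, sublingual and fat scores used for adjoining tissue were chosen after the data were seen. Within each group of 5 libraries, a value was set apart when its gap to the nearest other library was more than 0.71 of the range of the group. Of 450 groups of values 33 (7.33%) had such a library, where chance gives about 1 in 20.

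Clock genes differed between SJQYD and model glands in every library: the mean log2 CPM of clock-driven genes minus that of clock activators ran from 4.54 to 5.70 in the SJQYD group and from -3.51 to 0.85 in all other libraries. Tissue carried over from adjoining glands and fat is argued against as the whole cause, since with parotid, sublingual and fat scores in the fit 12 of 13 called clock genes stayed called in the same direction, and their mean absolute log2 fold change moved from 2.63 to 2.47. A difference in time of day of collection cannot be told apart from an effect of SJQYD on the clock, as both predict the gap of 3.68 between the lowest SJQYD library and the highest other library, and no label gives the hour. An effect of the treatment may stand behind the pattern as a hypothesis, and the sampling times would have to be known to weigh it.

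Some interferon and antigen presentation genes were called higher and some endoplasmic reticulum genes lower in model glands, and some of these lists' genes were called in the reverse direction after SJQYD. After SJQYD these were 5 of 32 type I interferon, 1 of 22 interferon gamma and 3 of 24 antigen presentation genes, which fell, and 6 of 24 endoplasmic reticulum genes, which rose (27, 11, 6 and 12 adjusted over the list alone, with 1 endoplasmic reticulum gene lower), and the camera calls were lost with an estimated correlation (adjusted p = 0.203, 0.264, 0.371 and 0.193). B and T cell share is argued against as the whole cause for type I interferon genes. With B and T cell scores in the fit the SJQYD score minus the model score moved from -0.90 ± 0.22 to -0.75 ± 0.21 (SE). The B and T scores differed by -1.03 ± 0.85 and -1.07 ± 0.91. The scores of cytotoxic and natural killer cells and of myeloid cells, which differed by -0.957 and -0.664, were not in the fit. The share of those cells was not tested and stays open. Adjoining tissue is argued against as the whole cause for the endoplasmic reticulum genes, whose score difference was 0.43 ± 0.12 without and 0.44 ± 0.15 with the tissue scores. Chance deviation of the shared model libraries stays open, since the covariance of the fold changes, -0.170, was beyond the simulated -0.139 to -0.109, but with the libraries split it ran from -0.127 to 0.0147, and the correlation, -0.357, was weaker than the simulated -0.535 to -0.462. The simulated ranges may also be too narrow, as each gene was drawn on its own. The number of 77 genes in opposite directions ran from 23 (without model 2) to 128 (without model 4). An effect of SJQYD is a candidate explanation, and so is any other difference between the groups that the labels do not give.

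Some large folds between model and control may come from reads assigned to another copy of a gene because of a strain variant. Among 131 called genes with a log2 fold change of at least 2 in size, 26 (19.8%) were pseudogenes, against 7.35% of the other tested genes (one-sided Fisher's exact test, p = 3.48e-06). Most of these large folds were thus not in pseudogenes, and the test did not match genes by expression level. For Ndufs5 the log2 ratio moved from -1.83 to -0.18 once the gene was summed with the pseudogene named after it, and for Rpl30 from -2.38 to -1.12 with 8 pseudogenes, which accounts for part. For Rpl26 it stayed at 5.05, which cannot be told apart, as the named copies held 0.00356% of the sum, so that another copy would go unseen. Summed with its copy, Ndufs5 stood at 39.3 ± 1.86 CPM in the model group and 44.4 ± 6.78 CPM in the control group (SD, n = 5 per group). This argues against a difference of expression between the strains as the whole cause of its fold. For Rpl30, Rpl26 and the other genes such a difference stays open and was not tested.

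Each count was set beside 100 splits of the same libraries into groups of 5, the real one included. For model against control 2 splits gave a count as large as 920 genes, the real one and another with 1443. Such a count was rare among the splits, yet a wrong grouping exceeded that of the real one. The splits alone therefore do not exclude chance for this number. That other split exchanged control 2 and model 4. Why it called more genes than the real one was not tested, apart from a swap. A swap of these 2 libraries is argued against by genes picked on the other 13 libraries, in which control and NOD/LTJ libraries lay at least 2-fold apart. In 90.6% of 64 such genes model 4 lay on the side of the NOD/LTJ libraries, and in 71.9% control 2 lay on the side of the controls, where a swap predicts the other side. With any other pair of 1 control and 1 model library held out the model library ran from 90.9% to 100% and the control library from 69.2% to 88.9%. With a gap of 0.5 on the log2 scale, 182 genes gave 84.6% for model 4 and 53.8% for control 2. Wider gaps of 1.5 and 2 gave 93.8% and 100% for model 4 and 81.2% and 88.9% for control 2. The place of control 2 was thus less clear with the narrowest gap. For SJQYD against model 1 split, the real one, gave 498 genes and the highest other gave 39. For SJQYD against control these numbers were 2017 and 126 (1 split). This argues against chance for these numbers of genes. It does not exclude it, as only 100 splits were used and the test was chosen after the result was seen. For lists in model against control, 2 splits gave as many as 21, the real one and another with 21. The other splits called a median of 11 lists, so chance is not excluded by this number. Nor could it be excluded for SJQYD against model. There 11 splits gave at least the 18 lists of the real one, and the highest other gave 26. For SJQYD against control chance could not be excluded either, as 29 splits gave at least 13 and the highest other gave 20. The other splits called a median of 9 lists in both of these comparisons. For the 77 genes in opposite directions the splits decide nothing, since a median of 0 genes was called in the regrouped comparison and so in most splits none could be called in both. As many as 77 were found in 2 splits with control and model libraries regrouped (highest other 694, the exchange of control 2 and model 4 again) and in 1 split with model and SJQYD libraries regrouped (highest other 12).

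Library measures set apart were a total of 39510018 counts in SJQYD 2 (others 55732445 to 62335235), a TMM factor of 1.85 in SJQYD 1 (others 0.910 to 1.17) and a Mucl2 share of 15.5% in SJQYD 1 (others 37.6 to 46.4%). The share of the 4 parotid genes stood apart at 4.17% in control 2, 16.0% in model 3 and 6.50% in SJQYD 1. Xist stood at 0.060 log2 CPM in SJQYD 3 (others 7.85 to 8.08).

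List scores set apart were, on the log2 scale, -2.13 for granular duct genes in model 4 (others -0.31 to 0.39), -0.15 for Toll-like receptor genes in control 1 (others 0.02 to 0.07), -0.35 for respiratory chain genes in model 5 (others -0.15 to -0.09), -0.70 for mitochondrial genes in control 2 (others 0.05 to 0.29), -0.073 for autophagy genes in SJQYD 4 (others -0.19 to -0.16) and -3.41 for sublingual genes in SJQYD 5 (others 0.50 to 1.42).

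Single genes, in log2 CPM, stood apart in the control group as follows. Klra7 and Cxcl13 were at -4.90 in control 3, where they had no count, Tpm3-rs7 at 3.55 in control 1, Chrm3 at 0.19 in control 5, Cd3e at 1.96 in control 2, Tef at -0.62 in control 1, Mir22hg at 2.39 in control 4, Oasl2 at 3.25 and Ctss at 4.69 in control 5, Vil1 at -0.90 in control 1 and BC018473 at 3.72 in control 3. In the model group these were Per1 at 5.43 in model 4, Mir22hg at 2.01 in model 1, Tjp3 at 6.25 in model 2 and Ceacam10 at 1.31 in model 4. In the SJQYD group they were Sphk1 at 3.21 and Rpl30 at 5.00 in SJQYD 3, Chrm3 at -0.64 in SJQYD 2, and Egf at 7.89 and Ceacam10 at -3.87 in SJQYD 5.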

How the results depend on the processing

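The fits with tissue scores as covariates and without the 3 libraries highest in parotid genes were chosen after seeing the data, and all other alternatives before. Of 132 called results for named genes, other normalizations on counts kept between 130 and 132 and DESeq2 kept 132. The fit of only the 2 groups compared kept 115, voom 123, no filter 118, tissue covariates 81 and the fit without the 3 libraries 103. Of 125 with FPKM values, log2(FPKM + 1) kept 90 and log2(FPKM + 0.1) kept 89, and without a filter 79 of 132 were kept. Leaving out a library kept between 105 (model 2) and 131 (control 2) of the 132. Causes of the changes below were not tested. By construction, stricter thresholds call fewer genes and FPKM values omit TMM factors. For the gene lists described, 67 camera values in these alternatives no longer passed, 1 turned and 284 stayed as they were, and with a library left out 47 no longer passed, 3 turned and 610 stayed as they were.

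Model against control gave 1779 genes with DESeq2, 466 with only the 2 groups compared, 1447 on log2(FPKM + 1), 1958 on log2(FPKM + 0.1), 555 on log2(FPKM + 1) with no filter, 220 with tissue covariates, 1507 without the 3 libraries, 363 at 2-fold or more and 186 at an adjusted p under 0.01. SJQYD against model gave 1072 with DESeq2, 68, 57 and 48 with the same FPKM settings, 186 without the 3 libraries, 127 at 2-fold or more and 160 at an adjusted p under 0.01. SJQYD against control gave 3626 and 4046 on filtered FPKM values, 609 with tissue covariates, 591 at 2-fold or more and 664 at an adjusted p under 0.01. Genes in opposite directions numbered 39 with no filter on low counts, 206 with DESeq2, 35 with only the 2 groups compared, 10, 8 and 7 with FPKM, 26 with tissue covariates, 35 without the 3 libraries, 11 at 2-fold or more and 7 at an adjusted p under 0.01. With FPKM values, scaled to total counts, 97.2%, 97.8% and 93.0% of model against control calls were higher, against 50.7%. In SJQYD against control these were 97.6%, 97.8% and 95.4%, against 47.0%. The median log2 fold change of all genes moved from 0.03 to 0.28 and 0.45 in the first and from 0.04 to 0.33 and 0.54 in the second.

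With an estimated correlation camera called 0, 1 and 0 lists in the 3 comparisons in the order above, and fry called 10 in SJQYD against model and 3 in SJQYD against control. List scores past the exact permutation test numbered 7 in model against control and 0 in SJQYD against model on log2(FPKM + 1), and 0 and 0 with medians over members. The lowest Spearman correlation was 0.897 with FPKM values, against 0.922.

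Without 1 library, model against control ran from 354 (model 2) to 1799 (control 2), with 410, 565, 543 and 590 without control 1, 3, 4 and 5 and 531, 601 and 548 without model 1, 3 and 5. SJQYD against model ran from 333 (model 2) to 527 (control 5). SJQYD against control ran from 1240 (control 5) to 2626 (control 2), with 1298 without SJQYD 2. Genes in opposite directions ran from 23 (model 2) to 128 (model 4), with 30, 45 and 41 without control 1, 3 and 4, 32, 35 and 40 without model 1, 3 and 5, and 51, 46 and 42 without SJQYD 1, 3 and 4. Lists ran from 16 (control 5) to 22 (control 3), from 15 (SJQYD 4) to 22 (SJQYD 5), and from 8 (control 3 and SJQYD 3) to 15 (control 2) in the 3 comparisons. List scores ran from 0 to 16 in model against control, with 0 without each of model 1, 2, 3, 4 and 5 and 16 without control 2, and from 0 to 7 in SJQYD against model, with 0 without model 1, model 5 and SJQYD 1.

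Replicate numbers do not pair the samples: over 15 pairs of libraries with the same number, correlations ran from -0.226 to 0.160, and 3 of them were best with their own number. With the number as a replicate block the counts were 896, 401 and 1799, with 112 of the 132 named results kept, 67 genes in opposite directions, and 20, 17 and 13 lists. Sign flips within the block gave 0 and 0 list scores, as the smallest p they allow cannot pass.

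Directions reversed for genes with small changes. In model against control Syvn1 was at 0.026 on log2(FPKM + 1) and 0.029 on log2(FPKM + 0.1), Aqp5 at 0.25 with FPKM values, and Chrm3 at 0.12 with voom, at 0.15 on log2(FPKM + 1) and at 0.43 on log2(FPKM + 0.1). In SJQYD against model Egf was at 0.13 without the 3 libraries and from -0.76 (without SJQYD 5) to 0.017 (without model 3). In SJQYD against control Ndufb3 was at 0.024 on log2(FPKM + 1) and 0.025 on log2(FPKM + 0.1). The endoplasmic reticulum list of this comparison, which camera did not call (adjusted p = 0.958), turned without the 3 libraries (adjusted p = 0.469) and without control 2, SJQYD 1 and SJQYD 5 (adjusted p = 0.638, 0.775 and 0.977), and was at most at 0.993 (without model 2).

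Camera calls lost without 1 library were, in model against control, those for Toll-like receptors without control 2, control 5 and model 1 (adjusted p = 0.0555, 0.0624 and 0.0901), granular duct without control 5 and model 4 (0.0513 and 0.0968), respiratory chain without control 5 (0.0856), adipocytes without control 2 and model 2 (0.0677 and 0.318) and nerve without control 1, 2 and 5, model 1 and 2 and SJQYD 2 (0.0524 to 0.103). In SJQYD against model they were those for B cells without SJQYD 4 (0.0552), T cells without model 1, model 5 and SJQYD 4 (0.0502, 0.0647 and 0.0534) and mitochondrial genes without control 1 and 5, model 2 and 4 and SJQYD 1, 2, 3 and 4 (0.0515 to 0.218). In SJQYD against control they were those for interferon gamma without control 1, 3 and 4 and SJQYD 2 and 3 (0.0538 to 0.151), antigen presentation without control 1, 3 and 4 and SJQYD 2, 3 and 5 (0.0614 to 0.135), T cells without control 3 and 4 and SJQYD 2 and 3 (0.0622 to 0.335) and mitochondrial genes without control 1, 3 and 4 and SJQYD 1, 2 and 3 (0.0549 to 0.112).

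Depth limited low genes: 3 counts, a floor that may be too low, correspond to 0.0290 (SJQYD 1) to 0.0840 CPM (control 1).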

Other observations

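The tests of KEGG sets and of the X chromosome were chosen after seeing the data. Exact permutation p values of KEGG set scores are not adjusted over the sets, whereas the camera values are. Of 290 KEGG sets, protein processing in the endoplasmic reticulum, with 155 genes tested, held 23 genes lower and 3 higher in model against control (camera adjusted p = 5.89e-10, adjusted p = 0.516 with an estimated correlation, exact permutation p = 0.0238 for its score). After SJQYD 20 of its genes were higher than in the model group and 1 lower (camera adjusted p = 4.68e-06, adjusted p = 0.477 with an estimated correlation, exact permutation p = 0.0317). Protein export, with 27 genes, held 8 lower genes in model against control (camera adjusted p = 1.91e-07, adjusted p = 0.516 with an estimated correlation). The natural killer cell cytotoxicity set, with 109 genes, held 11 higher and 2 lower genes in model against control (camera adjusted p = 1.73e-05, adjusted p = 0.516 with an estimated correlation).

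In SJQYD against control, oxidative phosphorylation, with 124 genes, held 21 lower genes and 1 higher (camera adjusted p = 6.2e-05, adjusted p = 0.67 with an estimated correlation, exact permutation p = 0.0556). The tight junction set, with 136 genes, held 20 lower and 4 higher genes (camera adjusted p = 0.0149, adjusted p = 0.261 with an estimated correlation).

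Xist stood at 1.01 CPM in SJQYD 3 and at 162 to 270.2 CPM in the other libraries. Y-linked genes had 11 counts in SJQYD 3 and 0 to 15 counts in the others. Deviations of X-linked genes were taken from the median of each gene over libraries, on the log2 scale. The median deviation of 216 such genes was -0.03 in SJQYD 3 and between -0.09 and 0.11 in the others. The mean deviation of 6 genes that escape X inactivation was -0.43 in SJQYD 3, the lowest of 15, with -0.37 in model 2.

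Rpsa, a ribosomal protein gene with 10 pseudogenes named after it, had a log2 ratio of model to control of 1.29 alone and of 0.11 summed with them.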
